A study of Mus musculus with 2 samples.

How the data were processed

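Single-nucleus RNA was measured in 2 mouse heart libraries, 1 per group (Control-NIL and Tnnt2-2D2P-NIL), from hearts with a myocardial infarction 7 days after injection. Per the labels' protocols, nuclei were released by homogenisation, passed through strainers, pelleted through sucrose and loaded on a droplet chip of 10x Genomics for 3' counting, with 2000 and 5000 nuclei named as targets per channel. The files hold 10699 and 12678 barcodes. The labels name a version 2 kit; whether the barcodes are of that kit was not tested. The values are whole-number UMI counts per gene and barcode, made with Cell Ranger 7.1.0 per the file headers, on the mm10 build per the submitters' processing notes. Whether intronic reads were counted, whether strand was used, and which annotation was used are not given in the sources used here. Coordinates come from a GRCm38 annotation (the same assembly as mm10), in which 32158 of the 32285 gene IDs of the files were found.

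Nuclei with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. This removed 79 control and 1 2D2P barcodes. Scrublet, as implemented in scanpy 1.11.5, was run per library with an expected rate of 0.08; its automatic threshold marked 0 nuclei in each library, so it did not work here. The nuclei at or above the score that cuts off the top 8% of a library's barcodes were removed instead, a fallback fixed before the data were examined. Scores tied at the cutoff were removed too, so more than 8% went. This removed 960 and 1111 nuclei that had passed the filter and left 9660 and 11566. Doublets can remain. Macrophage-like nuclei over 5000 UMIs held cardiomyocyte markers at 30499 CPM in the control and 41846 CPM in the 2D2P library. Shallower ones held 14679 and 18850 CPM. In endothelial-like nuclei the values were 17589 and 47845 CPM over 5000 UMIs, and 15456 and 18113 CPM in shallower ones. In fibroblast-like nuclei they were 13658 and 20173 CPM against 11477 and 12318 CPM.

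Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2) gave 32 clusters over both libraries without integration. A cluster was named from markers fixed beforehand when its mean marker score reached 0.7, at least 3 markers were present in at least 10% of its nuclei, and no class of another cell family reached both 0.7 and 0.6 of the best score. A cluster with at least 2 genes of kidney, airway or pigment cells among its 10 leading genes stayed unnamed. These scoring thresholds were set after the clusters had been seen, and 1 of them was raised so that an endothelial cluster was named when doublets were kept. The unnamed clusters were cluster 7, led by mitochondrial genes (9.24% of control and 0.0259% of 2D2P nuclei), cluster 14, led by airway and haemoglobin genes (0.0414% and 3.06%), cluster 21, with markers of more than 1 class (0% and 1.34%), and cluster 28, led by kidney genes (0.890% and 0%). A cluster with more markers of another class than of its own among its leading genes also stayed unnamed. Of the 28 named clusters 14 had 0 of their own markers among those genes, so their names rest on the score.

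UMIs were summed per library over the nuclei of a class and divided by the class total, and are given as CPM. The ratio of the libraries has an exact conditional binomial interval, CPM an exact Poisson interval and a share of nuclei an exact binomial (Clopper-Pearson) interval, all at 95%. No p-value was computed, because nuclei are not replicates. A gene was called measured with at least 20 UMIs over both libraries. A library with 0 UMIs of a gene was set to a floor of 3 counts over the class, which makes the ratio an approximate bound. The exact bound is that of the interval. Where that floor lay above the level in the other library, the bound has no direction, and the gene entered list medians at 0 and counted as neither higher nor lower; this treatment was added after the data were seen. The 33 gene lists, 4 of them used in every main class (45 pairs of list and class), were fixed before the data were examined, as were the comparisons between the libraries, the markers and the alternatives listed first below. Tests of explanations in the closing sections were fixed before or chosen after, as stated there. Each list's median was set against 10000 random lists matched over 20 bins of mean CPM, and its interval came from 1000 Poisson redraws.

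Named genes followed a rule fixed beforehand. By size, these were the 10 genes (cardiomyocytes) or 5 genes (other classes) with the highest lower bound of the ratio and as many with the lowest upper bound, among genes with at least 100 UMIs and at least 20 CPM in a library, leaving out genes far more abundant in another class, mitochondrial and haemoglobin genes, Xist, Y-linked genes and unnamed gene models. Other X-linked genes were kept. From each list, the measured members with the highest and the lowest ratio among those with at least 100 UMIs were named, then a fixed set of 15 cardiomyocyte genes, Xist and the Y-linked genes. Of the genes this rule names by size, 1 in cardiomyocytes and 1 in fibroblasts are not reported here. Genes of the closing observations were chosen after the data were seen. The gene lists of the closing sections (postnatal decline, adult cardiomyocyte, kidney and airway) were not among the 33 lists fixed beforehand. Cycling nuclei were those with at least 2 different G2/M genes after thinning to 1000 UMIs.

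The ratio step was tested on simulated counts with 200 changed genes per class. Of 100 genes changed 1.5-fold, 87% were recovered among cardiomyocytes (15442 genes), 92% among fibroblasts (14852), 86% among endothelial cells (12486) and 76% among macrophages (14165); of 100 genes changed 3-fold, 100%, 100%, 100% and 99%. Intervals of unchanged genes held a ratio of 1 in 95.6%, 95.8%, 96.0% and 96.3% of cases in the same order. The counts were drawn as Poisson counts from the pooled profile of each class, the model that the intervals assume. The simulation therefore checks the code and holds no spread between nuclei, hearts or preparations.

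The alternatives fixed beforehand were no filter on nuclei, a stricter filter (1000 UMIs, 5%), doublets kept, Leiden resolution 0.5, separate clustering of the libraries, TMM scaling (edgeR 4.0.16), a total without mitochondrial genes and Malat1, equal weight per nucleus, thinning, subtraction of free RNA, other minimum counts and other definitions of cycling. The free RNA estimate was 66.6% and 56.8% of UMIs in classes other than cardiomyocytes and 16.6% and 32.7% in cardiomyocytes. For the other classes it counts every cardiomyocyte marker UMI in macrophage-like nuclei as free RNA. For cardiomyocytes it counts every macrophage and fibroblast marker UMI in cardiomyocyte-like nuclei as free RNA. Doublets are included in both, so it is a severe setting. Nuclei with a Y-linked UMI and none of Xist (called male nuclei), and cardiomyocytes without clusters 17 and 19, were alternatives chosen after seeing the data. The name male nuclei stands for this rule only, since low depth can hide Xist and free RNA can add a Y-linked UMI. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.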

Results

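Hearts of mice with a myocardial infarction were collected 7 days after injection of Control-NIL or of Tnnt2-2D2P-NIL, nuclei were isolated, and the RNA of single nuclei was counted in droplets. Tnnt2, named in the label of the second treatment, encodes cardiac troponin T of the thin filament. What NIL and 2D2P stand for is not given in the labels. Each group had 1 library, so no difference has a replicate check. The values describe these 2 libraries and not the spread between hearts. The control library held 10699 barcodes and 48067499 UMIs (median 2699 per nucleus), and the 2D2P library held 12678 barcodes and 56147509 UMIs (median 3493). All intervals are exact 95% intervals, or for list medians intervals from Poisson redraws, and cover counting error only.

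The comparison asks which heart cells the libraries held and how the RNA of each class differed, in a study whose title concerns actin remodelling with loss and return of the mature state and with division of heart cells. Cardiomyocyte-like nuclei made up 16.6% (15.9 to 17.4) of control and 38.3% (37.4 to 39.2) of 2D2P nuclei, and macrophage-like nuclei 14.9% (14.2 to 15.6) of control and 3.80% (3.46 to 4.17) of 2D2P nuclei. Fibroblast-like nuclei were 26.3% (25.4 to 27.2) of control and 21.8% (21.1 to 22.6) of 2D2P nuclei, and endothelial-like nuclei 9.13% (8.56 to 9.72) of control and 8.92% (8.41 to 9.46) of 2D2P nuclei. Endocardial-like nuclei made up 6.70% (6.21 to 7.21) of control and 12.5% (11.9 to 13.1) of 2D2P nuclei, and mesothelial-like nuclei 7.63% (7.11 to 8.18) of control and 2.24% (1.98 to 2.53) of 2D2P nuclei. Lymphatic endothelial-like nuclei were 3.42% (3.06 to 3.80) of control and 0.259% (0.175 to 0.370) of 2D2P nuclei, while pericyte-like nuclei were 2.97% (2.64 to 3.33) of control and 3.04% (2.74 to 3.37) of 2D2P nuclei. The 4 clusters that no class could be given held 10.2% (9.58 to 10.8) of control and 4.43% (4.06 to 4.82) of 2D2P nuclei.

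**Figure D1:**
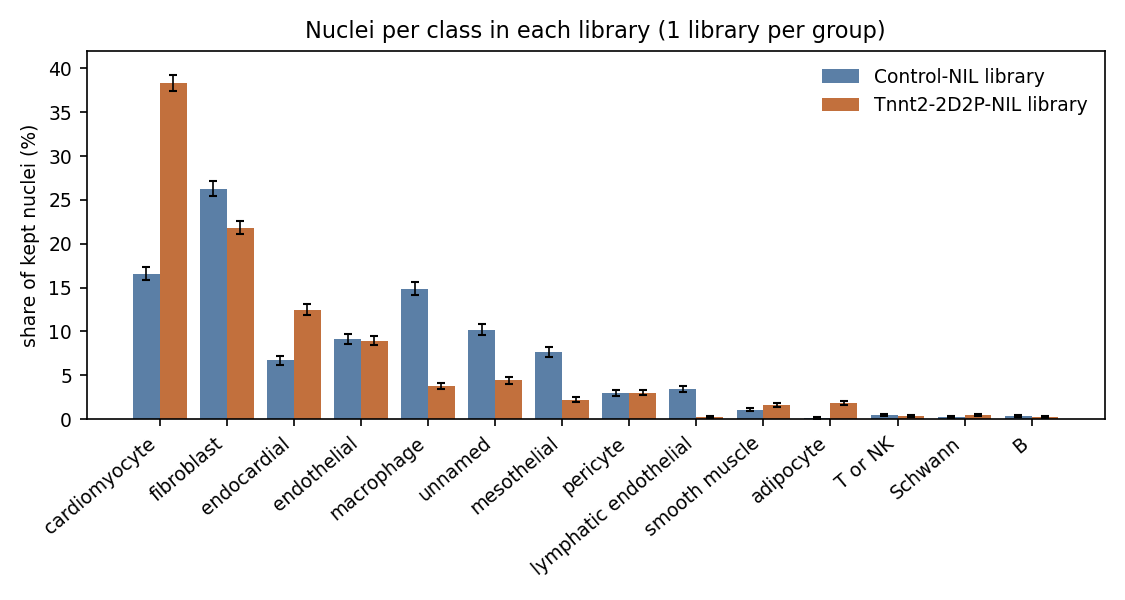
Share of kept nuclei (%) per class in each library, with bars for the share and error bars for the exact 95% binomial interval. Cardiomyocyte-like nuclei stand at 16.6% in the control library and 38.3% in the 2D2P library, and macrophage-like nuclei at 14.9% and 3.80%.

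The nuclei of the libraries clustered apart: 27 of 32 clusters drew at least 90% of their nuclei from 1 library. A cluster mostly of 1 library may be that library and not a type. Cardiomyocyte-like nuclei lay mostly in clusters 2 and 30 in the control library and in clusters 0, 17 and 19 in the 2D2P library. Fibroblast-like nuclei lay mostly in clusters 5 and 6 against 1, 24 and 26, endothelial-like nuclei in cluster 8 against 9 and 23, and macrophage-like nuclei mostly in cluster 3 against 12. The median mitochondrial share was 0.499% per control barcode and 0.118% per 2D2P barcode. Shares of nuclei can follow the recovery of each nuclear preparation.

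In cardiomyocyte-like nuclei, genes of cell division were at a far higher level in the 2D2P library. Top2a, which encodes the topoisomerase that untangles replicated chromosomes, was 92.4-fold higher (46.8 to 214), with 57.7 against 0.624 CPM, and Mki67, a marker of dividing cells, was 65.2-fold higher (33.0 to 152). Much of this lay in few nuclei: cluster 19, with 230 of the 4433 2D2P nuclei, held 1031 of their 1301 Top2a UMIs and 603 of their 918 Mki67 UMIs. Without clusters 17 and 19 the log2 ratios of Top2a and Mki67 were 4.13 and 4.49 and the medians of the G2/M and S phase lists were 2.96 and 2.25. Of the measured G2/M genes 29 of 30 and of the S phase genes 25 of 26 were higher, with median log2 ratios of 4.75 (4.47 to 5.09, percentile 100) and 2.96 (2.51 to 3.15, percentile 100). The percentile is the rank of a list's median among 10000 random lists matched on expression. Counts of higher and lower members go by the ratio alone, whatever its interval. Ckap2 and Knl1, which act at the spindle and the kinetochore, were at least 74.4-fold higher by the exact bound and 71.2-fold higher (37.4 to 156). With clusters 17 and 19 left out, their log2 ratios in cardiomyocyte nuclei were 4.13 and 3.45, and those of Ttk and Cenpa were 4.52 and -0.77. Ttk and Dtl, the highest members of the G2/M and S phase lists, had 7.54 against 0.0780 CPM and 15.3 against 0.156 CPM, and the lowest members, Cenpa and Ung, had 59.0 against 60.1 CPM and 10.7 against 11.7 CPM. In the cell cycle entry list 10 of 12 genes were higher (median 1.66 (1.24 to 1.85, percentile 100)), among them E2f1, a transcription factor of S phase genes, at 6.78 against 0.468 CPM. The D-type cyclins that drive entry into the cycle differed less: Ccnd2 was 2.77-fold higher (2.46 to 3.13), Ccnd1 1.95-fold higher (1.48 to 2.59) and Ccnd3 1.14-fold lower (1.03 to 1.25). The cell cycle inhibitor list had a median of 0.31 (0.27 to 0.52, percentile 74.7), or -0.03 in nuclei thinned to 1000 UMIs, with Rbl1 7.12-fold higher (4.96 to 10.6) and Cdkn1a, which encodes p21, 1.67-fold lower (1.36 to 2.04).

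Genes of the stressed and the immature heart muscle cell went in different directions. Tnni1, the slow skeletal troponin I that the fetal heart uses, had 4712 against 0 UMIs in the 2D2P and control libraries. It was 893-fold higher against a floor of 3 counts, with an exact lower bound of 726-fold. Nppb and Nppa, the natriuretic peptide genes, were 8.76-fold lower (7.97 to 9.65) and 1.97-fold lower (1.86 to 2.09). Myh7, the slow myosin heavy chain, was 3.10-fold lower (2.98 to 3.22), Acta1, skeletal actin, 8.98-fold lower (7.56 to 10.7), and Ankrd1 1.86-fold lower (1.81 to 1.91), while Acta2, smooth muscle actin, was 10.1-fold higher (9.10 to 11.3). Over the fetal and stress list 8 of 13 genes were lower, with a median of -0.98 (-1.06 to -0.90, percentile 0). In the dedifferentiation list 8 of 11 genes were higher (median 1.35 (1.17 to 1.70, percentile 100)). After subtraction of free RNA this median was 0.00, and fibroblast markers summed to 951 CPM in the 2D2P and 462 CPM in the control cardiomyocyte-like nuclei. A gene that the subtraction took to 0 in both libraries entered at 0, so a median of 0.00 does not show that the difference went away. The highest member of the dedifferentiation list was the RNA-binding protein gene Igf2bp3, at 57.0 against 1.64 CPM, and the lowest the transcription factor gene Runx1, at 7.09 against 42.1 CPM.

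The sarcomere genes went in both directions. Myh6, the adult fast myosin heavy chain, had 8778 against 12628 CPM, and Tnnt2 had 3514 against 4171 CPM, which is 1.19-fold lower (1.17 to 1.20). The adult sarcomere list had 11 of 19 genes lower and a median of -0.25 (-0.26 to -0.21, percentile 5.09); the titin cap gene Tcap was 6.02-fold lower (5.60 to 6.48) and the light chain gene Myl3 1.80-fold higher (1.74 to 1.86). Of the actin remodelling list 46 of 53 genes were higher (median 0.50 (0.44 to 0.54, percentile 99.99)). Diaph3, a formin that lengthens actin filaments, was 15.4-fold higher (11.6 to 20.7), with a log2 ratio of 2.85 without clusters 17 and 19 against 3.94 with them. Actb, cytoplasmic beta actin, was 1.64-fold higher (1.56 to 1.72), and Lmod2, which elongates sarcomeric thin filaments, 3.03-fold lower (2.91 to 3.16). Actg1 had 548 against 558 CPM, a difference within its counting interval. The SRF and MRTF target list had 10 of 16 genes higher (median 0.18 (0.06 to 0.48, percentile 64.52)), from Myl9, 27.5-fold higher (20.7 to 37.4), to Acta1. The YAP and TEAD target list had 9 of 14 genes lower (median -0.31 (-0.40 to -0.11, percentile 1.36)), from Ccn1, 8.07-fold lower (6.38 to 10.3), to Ajuba, 2.58-fold higher (1.70 to 4.03).

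Genes of fatty acid oxidation and of oxidative phosphorylation were higher as groups. In the fatty acid oxidation list 20 of 24 genes were higher (median 0.79 (0.73 to 0.85, percentile 100)), led by Pdk4, the kinase that restrains pyruvate dehydrogenase, at 159 against 13.1 CPM, with lipoprotein lipase, Lpl, 1.87-fold lower (1.81 to 1.94). The oxidative phosphorylation and TCA cycle list had 20 of 26 genes higher (median 0.52 (0.47 to 0.54, percentile 99.95)), from Cox5a, 1.91-fold higher (1.79 to 2.04), to Cox7a1, 1.40-fold lower (1.24 to 1.58). The glycolysis list had 15 of 21 higher (median 0.41 (0.18 to 0.54, percentile 97.1)), from Eno1, 2.18-fold higher (2.00 to 2.37), to Pfkfb2, 2.58-fold lower (2.43 to 2.73), but in nuclei thinned to 1000 UMIs its median was 0.14, near the 0.16 of all genes. Mitochondrially encoded RNA was 989 CPM in the 2D2P and 2591 CPM in the control cardiomyocyte-like nuclei.

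Several cardiomyocyte lists lay nearer to the median of all 15462 measured genes, 0.16. The calcium handling and ion channel list had 13 of 20 genes higher (median 0.15 (0.13 to 0.20, percentile 73.92)), from the calcium pump regulator Sln, 245 against 1 UMIs, to the potassium channel gene Kcnj3, 2.69-fold lower (2.57 to 2.81). Cluster 17 held 105 of the 245 Sln UMIs, and without clusters 17 and 19 the log2 ratios of Sln and Kcnj3 were 4.84 and -2.30. The cardiac transcription factor list had 10 of 14 higher (median 0.24 (0.16 to 0.32, percentile 85.84)), from Tbx20, 2.34-fold higher (2.25 to 2.43), to Hand2, 1.46-fold lower (1.29 to 1.65). The intercalated disc and costamere list had 13 of 20 higher (median 0.24 (0.20 to 0.26, percentile 88.15)), from Ctnna3, 1.83-fold higher (1.81 to 1.84), to Itga7, 1.67-fold lower (1.49 to 1.87). The receptor list had 11 of 16 higher (median 0.23 (0.18 to 0.30, percentile 71.68)), from Igf1r, 2.20-fold higher (2.12 to 2.28), to Osmr, 2.25-fold lower (1.89 to 2.69). The p53 and DNA damage list had 11 of 15 higher (median 0.19 (0.08 to 0.44, percentile 57.28)), from Phlda3, 2.96-fold higher (1.99 to 4.53), to Sesn1, 2.16-fold lower (2.08 to 2.24). Lower on balance were the integrated stress and redox list (11 of 17, median -0.51 (-0.73 to -0.16, percentile 0.66)), with Ddit4 3.02-fold lower (2.34 to 3.93) and Gclm 1.80-fold higher (1.43 to 2.29), and the interferon list (20 of 24, median -0.74 (-0.91 to -0.50, percentile 0)), with Trim30a 4.30-fold lower (3.27 to 5.72) and Eif2ak2 1.84-fold higher (1.59 to 2.15). The interferon median was 0.00 after subtraction of free RNA and -0.27 in nuclei thinned to 1000 UMIs, and macrophage markers summed to 54.8 CPM in the 2D2P and 138 CPM in the control cardiomyocyte-like nuclei. Genes that the subtraction took to 0 in both libraries entered at 0, so the 0.00 does not show that the difference went away. The immediate early and heat shock list had 11 of 17 lower (median -0.19 (-0.39 to -0.01, percentile 5.23)), with Zfp36 2.53-fold lower (1.73 to 3.74) and Ier2 1.78-fold higher (1.26 to 2.58).

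Among single genes, the largest ratios by the bound of their interval were, besides Tnni1, Ckap2, Top2a and Knl1, those of the potassium channel gene Kcnh7 (103-fold higher), the lysophosphatidic acid receptor gene Lpar3 (91.5-fold), Fgf12 (54.4-fold), the relaxin receptor gene Rxfp1 (64.1-fold), the calcium release channel gene Ryr3 (47.5-fold) and the airway secretory gene Scgb3a2 (455 against 1 UMIs). Kcnh7, Fgf12 and Ryr3 are leading genes of cluster 17, an atrial-like cluster with 278 2D2P and 2 control nuclei. Without clusters 17 and 19 their log2 ratios in cardiomyocyte nuclei were 3.90, 2.53 and 2.69. Lowest were Kap, a gene of the kidney proximal tubule (0 against 279 UMIs, at least 132-fold lower by the exact bound), Ctla4 (28.2-fold lower), the potassium channel gene Kcnd3 (23.6-fold), Art1 (21.9-fold), Plet1os (20.7-fold), Rmst (19.1-fold), Ccbe1 (17.9-fold), Prune2 (13.1-fold) and Rpl3l, a ribosomal protein gene of adult muscle (11.7-fold). In the mm10 build Tnni1 (ENSMUSG00000026418, chromosome 1 from 135779434 to 135810989) and Tnnt2 (ENSMUSG00000026414, chromosome 1 from 135836354 to 135852260) lie near each other on the same strand. Myh7 (ENSMUSG00000053093, chromosome 14 from 54970684 to 54994626) overlaps Mhrt on the other strand, as Plet1os does Plet1, Kcnd3 does Kcnd3os and Ctnna3 does Lrrtm3, so reads of these partners could be mixed. The same holds for the near-identical actin genes and for Myh6 and Myh7. TMM scaling shifted the median log2 ratio of all cardiomyocyte genes by -0.16, to 0.01, and set the calcium handling list at -0.01 and the adult sarcomere list at -0.41. The G2/M and S phase lists had medians of 2.85 and 1.75 in nuclei thinned to 1000 UMIs.

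**Figure D2:**
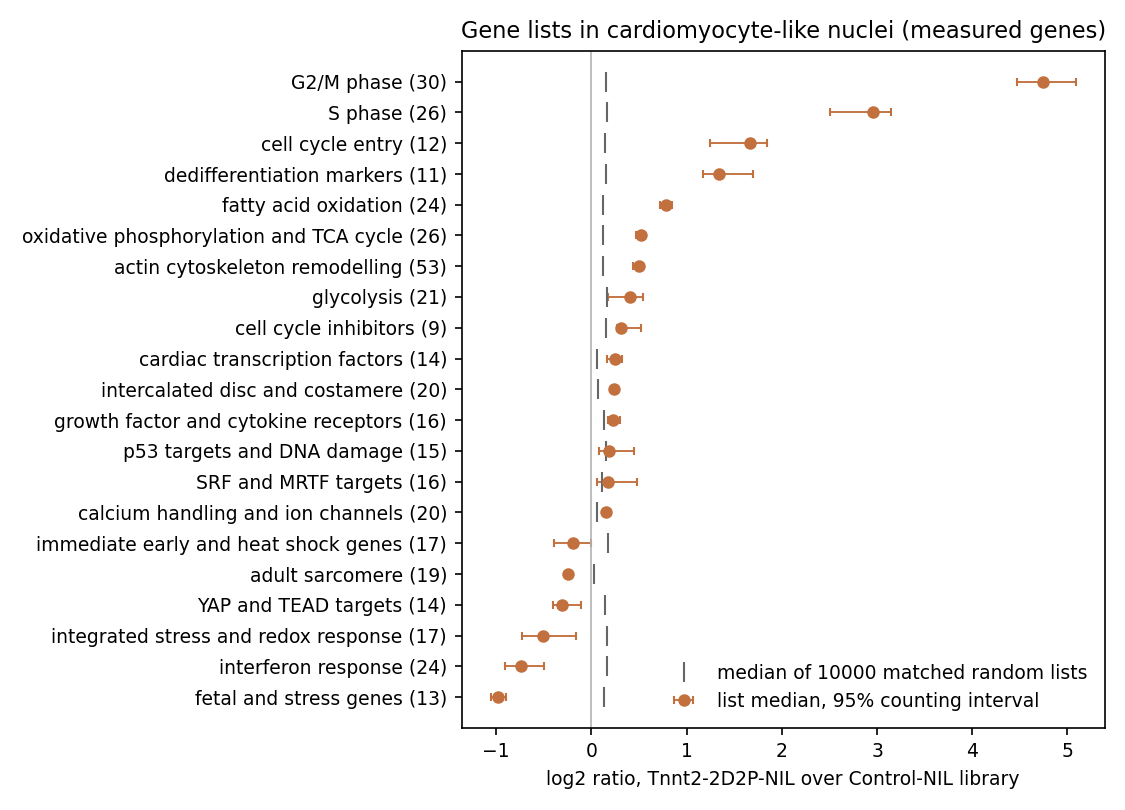
Median log2 ratio (2D2P over control library) of each gene list in cardiomyocyte-like nuclei, with points for the median, error bars for the 95% interval of Poisson redraws, ticks for the median of 10000 matched random lists, and the number of measured genes in parentheses. The G2/M list lies at 4.75 and the fetal and stress list at -0.98; the calcium handling list, at 0.15, lies at -0.01 under TMM scaling.

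Nuclei with transcripts of at least 2 different G2/M genes, after every nucleus was thinned to 1000 UMIs, were more frequent in the 2D2P library in each of the 4 main classes. They were 4 of 1602 cardiomyocyte-like nuclei in the control library (0.250%, 0.0681 to 0.638) and 264 of 4433 in the 2D2P library (5.96%, 5.28 to 6.69). Among endothelial-like nuclei the shares were 0.917% and 21.2%, among fibroblast-like nuclei 0.396% and 8.18%, and among macrophage-like nuclei 1.62% and 19.9%. With doublets kept the endothelial shares were 0.717% and 9.08% and the fibroblast shares 0.289% and 3.80%. In that setting a cluster led by cell cycle genes, with 362 2D2P and 5 control nuclei, stayed unnamed. No cluster led by such genes was named endothelial or fibroblast, so the lower shares can follow from nuclei that left these classes. Pericyte-like nuclei gave 0.353% and 14.4%, and endocardial-like nuclei 0.310% and 3.46%. Thinning left out 1 control and 0 2D2P cardiomyocyte-like nuclei; without it their shares were 6.55% and 25.1%, at median depths of 6596 and 4477 UMIs. Free RNA and doublets can add G2/M transcripts to a nucleus, and without cluster 19, led by cell cycle genes, and cluster 17 the difference between the libraries was 1.48 percentage points.

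**Figure D3:**
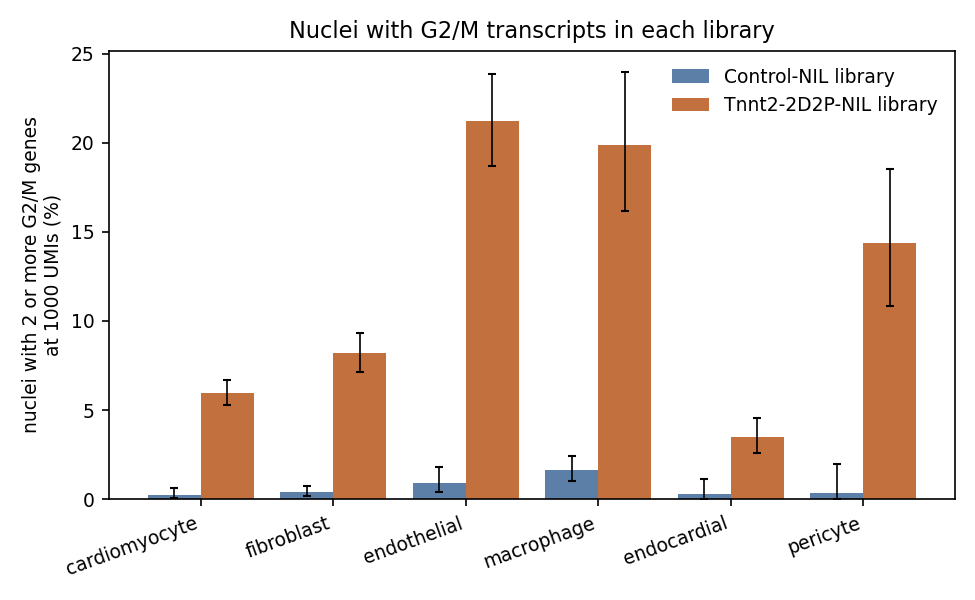
Share of nuclei (%) with at least 2 G2/M genes after thinning to 1000 UMIs, per class and library, with exact 95% binomial intervals. Cardiomyocyte-like nuclei stand at 0.250% in the control library and 5.96% in the 2D2P library, and endothelial-like nuclei at 0.917% and 21.2%.

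In fibroblast-like nuclei, genes of the late scar were far lower in the 2D2P library. Comp, a cartilage matrix protein gene of mature scar, was 66.5-fold lower (47.9 to 95.2), with 4.55 against 303 CPM, and 9 of 9 measured genes of its list had a ratio below 1 (median -2.87 (-3.23 to -2.47, percentile 0); -4.11 in male nuclei), up to Sfrp2, 1.73-fold lower (1.39 to 2.15). The fibrillar matrix list differed little: 13 of 24 genes were higher (median 0.07 (0.02 to 0.10, percentile 65.69)), with elastin, Eln, 2.10-fold higher (2.04 to 2.17) and biglycan, Bgn, 2.02-fold lower (1.89 to 2.15). The activated fibroblast list had 8 of 16 genes higher (median -0.02 (-0.12 to 0.09, percentile 33.16)), from Acta2, 3.32-fold higher (2.76 to 4.00), to the collagen gene Col8a1, 21.4-fold lower (20.01 to 23.0). The resting fibroblast list had 10 of 15 lower (median -0.06 (-0.15 to -0.04, percentile 25.3)), from Pi16, 7.60-fold lower (6.93 to 8.35), to Tcf21, 2.78-fold higher (2.27 to 3.43), and the TGF-beta list 8 of 15 lower (median -0.03 (-0.12 to 0.07, percentile 32.45)), from Ltbp2, 6.72-fold lower (6.01 to 7.52), to Tgfb2, 2.63-fold higher (2.39 to 2.90). Of the interferon genes 28 of 28 had a ratio below 1 (median -2.14 (-2.30 to -1.88, percentile 0)), with Ifit1 16.6-fold lower (7.77 to 42.4) and Ifit2 at 16.7 against 19.6 CPM, within its counting interval. In the G2/M and S phase lists 30 of 30 and 26 of 26 genes had a ratio above 1 (medians 3.35 (3.15 to 3.67, percentile 100) and 1.68 (1.51 to 2.01, percentile 100), or 2.39 and 1.27 with doublets kept), with Cdk1 at 12.9 against 0.446 CPM, Dtl at 19.7 against 1.49 CPM, Cenpa at 25.7 against 12.2 CPM and Mcm7, within its counting interval, at 14.5 against 11.4 CPM. With doublets kept, a cluster led by cell cycle genes stayed unnamed and its nuclei were in no class. The immediate early list had 11 of 16 lower (median -0.43 (-0.65 to -0.23, percentile 1.19)), with Junb 3.70-fold lower (2.71 to 5.12) and Jund 1.78-fold higher (1.53 to 2.08). By size, Nrk (38.2-fold), Hpse2 (53.2-fold), Rtl4 (79.0-fold), Tnni1 (108-fold) and Scgb3a2 (277 against 2 UMIs) were highest, and the complement gene C7 (52.4-fold), Ifi205 (68.2-fold) and Kap (0 against 326 UMIs) lowest with Comp. Nrk and Rtl4 lie on the X chromosome, whose Xist differs between the libraries. Cardiomyocyte markers summed to 13946 CPM in the 2D2P and 11731 CPM in the control fibroblast-like nuclei, and macrophage markers to 109 and 419 CPM, the same direction as the interferon genes, and mitochondrially encoded RNA to 1655 and 5741 CPM. After subtraction of free RNA the interferon median stayed inside its main interval and the fibrillar matrix median was -0.16. Tnni1, at 209 CPM in 2D2P cardiomyocyte-like nuclei, is a gene of that class.

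In endothelial-like nuclei, the endothelial activation list, with 6 of its 12 genes measured, was lower in the 2D2P library. The list includes Vwf, also among the endocardial markers, and is not a list of inflammatory genes alone. Of the measured genes of the activation list 6 of 6 had a ratio below 1 (median -1.12 (-1.43 to -0.88, percentile 0.14); -0.31 with the libraries clustered separately and -0.51 at a minimum of 100 UMIs), from von Willebrand factor, Vwf, 3.97-fold lower (3.23 to 4.89), to the nitric oxide synthase gene Nos3, at 196 against 204 CPM, within its counting interval. Of the interferon genes 24 of 24 had a ratio below 1 (median -1.60 (-1.73 to -1.40, percentile 0)), with the RNA sensor gene Ifih1 3.64-fold lower (2.57 to 5.22) and Eif2ak2, within its counting interval, at 66.0 against 66.5 CPM. The angiogenesis list had 12 of 19 genes lower (median -0.25 (-0.32 to -0.07, percentile 3.37)), with Plvap 2.65-fold lower (1.81 to 3.92) and the netrin receptor gene Unc5b 2.00-fold higher (1.70 to 2.38). The capillary lipid transport list had 7 of 11 higher (median 0.17 (-0.02 to 0.28, percentile 78.11)), with the fatty acid binding protein gene Fabp5 2.77-fold higher (2.22 to 3.49) and Lpl 1.77-fold lower (1.61 to 1.94). Ratios above 1 were found for 30 of 30 G2/M and 26 of 26 S phase genes (medians 3.89 (3.45 to 4.09, percentile 100) and 2.16 (1.84 to 2.68, percentile 100), or 2.91 and 1.68 with doublets kept), with Bub1b at 36.0 against 0.923 CPM, Dtl at 31.9 against 0.923 CPM, Cenpa at 61.3 against 25.9 CPM and Mcm6 at 37.9 against 19.4 CPM. The S phase median was 1.1 in male nuclei and 1.44 at a minimum of 100 UMIs. With doublets kept, a cluster led by cell cycle genes stayed unnamed, with endothelial as its best class, and its nuclei were in no class. The immediate early list had 11 of 15 lower (median -0.93 (-1.03 to -0.38, percentile 0.02); -0.17 at a minimum of 100 UMIs), with Dusp1 1.95-fold lower (1.52 to 2.51) and Jund 1.74-fold higher (1.34 to 2.28). By size, Top2a (35.0-fold), Neil3 (31.0-fold), Igf2bp3 (249 against 3 UMIs), Tnni1 (46.9-fold) and Scgb3a2 (119 against 0 UMIs) were highest, and the xanthine dehydrogenase gene Xdh (60.4-fold), Comp (44.2-fold), Oas2 (38.0-fold), H2-Q6 (24.3-fold) and Kap (0 against 101 UMIs) lowest. Tnni1 is a gene of cardiomyocytes and Comp a leading gene of control fibroblast cluster 6. Cardiomyocyte markers summed to 29912 CPM in the 2D2P and 15855 CPM in the control endothelial-like nuclei, macrophage markers to 149 and 612 CPM, the same direction as the interferon genes, and mitochondrially encoded RNA to 3157 and 11514 CPM. Nuclei over 5000 UMIs were 5.67% of the control and 13.5% of the 2D2P endothelial-like nuclei. They held cardiomyocyte markers at 17589 CPM in the control and 47845 CPM in the 2D2P library. Shallower ones held 15456 and 18113 CPM, so doublets can remain in this class. The angiogenesis median was 0.00 with doublets kept and -0.64 after subtraction of free RNA. The interferon median stayed inside its main interval after that subtraction.

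In macrophage-like nuclei, genes of antigen presentation were lower in the 2D2P library. H2-Eb1, an MHC class II chain gene, was 9.88-fold lower (5.17 to 21.7), and 9 of 12 genes of the list were lower (median -1.50 (-1.79 to -1.20, percentile 0)), while the costimulatory receptor gene Cd86 was 1.75-fold higher (1.52 to 2.02). Of the resident macrophage list 7 of 12 genes were higher (median 0.07 (-0.06 to 0.21, percentile 55.79)), with the mannose receptor gene Mrc1 2.23-fold higher (2.11 to 2.37) and the haemoglobin scavenger receptor gene Cd163 3.50-fold lower (2.75 to 4.54). The lipid and repair list had 9 of 13 lower (median -0.38 (-0.59 to -0.21, percentile 2.66)), with Gpnmb 13.6-fold lower (6.20 to 37.2) and Fabp5 3.54-fold higher (2.81 to 4.46). In the inflammatory monocyte list 6 of 11 genes were higher (median 0.21 (-0.18 to 0.32, percentile 90.5)), with the interleukin-1 beta gene Il1b at 13.6 against 10.4 CPM and Thbs1 2.46-fold lower (1.49 to 4.37). This last median was -0.67 with the libraries clustered separately and 0.63 in male nuclei, and its interval holds 0. The interferon list had 26 of 27 lower (median -0.87 (-1.16 to -0.66, percentile 0)), with Ifit1 at 2 against 101 UMIs and Trim30a at 165 against 178 CPM. In the G2/M and S phase lists 26 of 26 and 25 of 25 genes had a ratio above 1 (medians 3.45 (3.21 to 3.67, percentile 100) and 1.84 (1.56 to 2.13, percentile 100)), with Kif15 19.9-fold higher (13.5 to 29.9), Brip1 5.80-fold higher (4.20 to 7.98), Cenpa 2.10-fold higher (1.63 to 2.66) and Mcm7, within its counting interval, at 13.6 against 10.2 CPM. The immediate early list had 11 of 17 lower (median -0.52 (-0.79 to 0.00, percentile 2.25)), with Zfp36 3.17-fold lower (1.31 to 9.95) and Jund 1.58-fold higher (1.21 to 2.05). By size, Tnni1 (110 against 3 UMIs), Igf2bp3 (34.6-fold), Igf2 (28.9-fold), Neil3 (20.7-fold) and Kif15 were highest, and Itgbl1 (16.2-fold), Comp (26.5-fold), Art1 (2 against 664 UMIs), Ccn5 (0 against 352 UMIs) and Kap (0 against 271 UMIs) lowest. Tnni1 is a cardiomyocyte gene, Comp and Ccn5 are leading genes of control fibroblast cluster 6 and Art1 of control cardiomyocyte cluster 2. Itgbl1 is a member of the activated fibroblast list. Nuclei over 5000 UMIs, which held more cardiomyocyte markers than shallower ones, were 30.9% of the control and 11.8% of the 2D2P macrophage-like nuclei. Cardiomyocyte markers summed to 26028 CPM in the 2D2P and 26131 CPM in the control macrophage-like nuclei, endothelial markers to 1397 and 2769 CPM, and mitochondrially encoded RNA to 1756 and 7849 CPM. The 2D2P sum rested on 440 nuclei and 1251686 UMIs against 1436 nuclei and 8304947 UMIs.

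Transcripts of the sex chromosomes differed between the libraries. Xist, the RNA that silences an X chromosome in female cells, had 555 against 1.01 CPM in cardiomyocyte-like nuclei, 616 against 0.595 CPM in fibroblast-like, 541 against 0.462 CPM in endothelial-like and 679.9 against 0.241 CPM in macrophage-like nuclei. The Y-linked genes were present in both libraries: in cardiomyocyte-like nuclei Ddx3y had 58.4 against 93.5 CPM, Uty 151 against 196 CPM, Kdm5d 35.0 against 51.7 CPM and Eif2s3y 73.7 against 98.2 CPM. The other classes held Ddx3y at 59.4 against 112 CPM (fibroblast-like), 65.7 against 134 CPM (endothelial-like) and 73.5 against 126 CPM (macrophage-like). Xist overlaps Tsix on the other strand.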

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

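The tests on nuclei of 1 kind and on kidney RNA were chosen after the values they use, or part of them, had been seen; the test on pooled hearts was fixed before.

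Signal appeared in nuclei that the comparisons between classes do not use. Cluster 14, led by the airway genes Cyp2f2, Scgb3a1 and Scgb3a2 and by haemoglobin genes, held 3.06% of the 2D2P nuclei and 0.0414% of the control nuclei, with Scgb3a2 at 239 CPM and Hbb-bs at 743 CPM in the 2D2P library. Cluster 21, led by A2m, Plppr5, Ndst3 and Frem1 with H19 among its leading genes, held 1.34% of the 2D2P nuclei and 0% of the control nuclei. The airway secretory list had a median log2 ratio of 5.16 in cardiomyocyte-like, 4.45 in fibroblast-like, 3.71 in endothelial-like and 5.98 in macrophage-like nuclei. Of the measured genes 6 of 7, 6 of 7, 4 of 5 and 2 of 3 were higher, in the same order. A gene can count as measured through the 2D2P library alone, so these counts lend little weight.

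Xist and the Y-linked genes were both present in the 2D2P library. Of 4387 cardiomyocyte-like nuclei thinned to 2000 UMIs, 1964 held Xist, 1869 a Y-linked UMI and 547 both, where independence gives 837, so the ratio of observed to expected was 0.654 (0.6001 to 0.711), against 0.718 (0.638 to 0.805) in fibroblast-like, 0.768 (0.610 to 0.954) in endothelial-like and 0.760 (0.540 to 1.04) in macrophage-like nuclei. The cardiomyocyte value, below 0.8, and the fibroblast interval, below 0.9 but not below 0.8, argue against nuclei of 1 kind that all hold both transcripts, which need a ratio between 0.9 and 1.1; the endothelial and macrophage intervals reach past 0.9 and leave it open there. Hearts of male and female mice pooled in 1 library remain open: the bounds fixed for that explanation were below 0.5 and at least 0.9, and the value lies between them, while free RNA and doublets can add transcripts of the other kind to a nucleus. In the control library 4 of 1592 cardiomyocyte-like nuclei held Xist at the same depth. Sex-chromosome transcripts therefore went together with the group in the comparisons between the libraries. No biological explanation was tested, and the labels used here give no sex.

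Kap, a kidney gene, had 21.8 to 48.5 CPM in the 4 main classes of the control library and 0 UMIs in those of the 2D2P library, beside 86 kidney-like nuclei of cluster 28 in the control library that held Kap at 3302 CPM and Slc34a1 at 2878 CPM. Free RNA with the composition of those nuclei is argued against: Kap had 5.43 UMIs (4.63 to 6.40) per Slc34a1 UMI in the main classes and 1.15 (1.07 to 1.23) in cluster 28. Free RNA from kidney cells, cytoplasm included, remains open and may account for the pattern. Kap differed by 2.23-fold between the classes in CPM, with 114 to 189 UMIs per 1000 nuclei. Its ratio to Slc34a1 lay between 4.39 and 6.80 in all 4. In cardiomyocyte-like nuclei 5 of 5 other measured kidney genes were higher in the control library. A gene can reach the 20 UMIs needed through the control library alone, so the counts of kidney genes lend little weight. Of the 12 genes of the kidney list, 6 were measured in cardiomyocyte-like nuclei, with a median of -3.34, against -3.27 in fibroblast-like, -3.50 in endothelial-like and -1.44 in macrophage-like nuclei. In the 2D2P library 6 of 6, 6 of 6, 5 of 5 and 5 of 7 measured genes were lower, in that order. Of the measured genes 2 of 7 were higher in macrophage-like and 2 of 4 in endocardial-like nuclei.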

How the results depend on the processing

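The alternatives that kept only male nuclei, or left out cardiomyocyte clusters 17 and 19, were chosen after seeing the data; the others were planned. Of 24 alternative values of the class shares 16 stayed inside the main counting interval and 0 changed sign where that interval left out 0, of 41 of the cycling shares 21 and 0, of 606 of the list medians 482 and 4, and of 1912 of the gene ratios 1629 and 10. Results whose main interval held 0 are not in these counts of sign changes: the difference in the endothelial share, -0.208 points, was 0.797 points with the libraries clustered separately. The signs of the capillary lipid transport, activated fibroblast, resident macrophage and inflammatory monocyte medians likewise depended on the setting. The G2/M and S phase medians were above 0 and the fetal and stress, late scar and antigen presentation medians below 0 under all alternatives run for them. The cause of the values that changed was not tested. By construction, other minimum counts and thinning alter which genes are measured, and male nuclei are picked by the Y-linked genes themselves. The Ccnd3 value after subtraction rests on a control count taken to the floor. A gene that the subtraction took to 0 in both libraries entered list medians at 0, so medians of 0.00 under that setting can rest on such genes. No paired analysis was possible because each group had 1 library. Leaving out a channel was not run because the barcodes of each library carry 1 channel suffix, and leaving out a library leaves no comparison. Depth limits the macrophage ratios, since the 2D2P sum held 1251686 UMIs against 8304947 in the control library.

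The shares and list medians that left the main interval, and the gene ratios that changed sign where it left out 0, were these, as log2 medians or ratios unless given as percentage points. The other 273 gene ratios outside their main intervals kept their sign or had an interval that held 0, and are not listed. No filter on nuclei gave, in endothelial cells, G2/M 4.10, angiogenesis -0.01 and capillary lipid transport 0.30. The stricter filter on nuclei gave differences of -12.1 points (macrophage share). For endothelial cells it gave G2/M 4.10. Doublets kept gave differences of 17 points (cardiomyocyte share), -1.65 points (endothelial share), -14.2 points (macrophage share), 3.51 points (cycling fibroblast nuclei) and 8.36 points (cycling endothelial nuclei). In cardiomyocytes it gave adult sarcomere -0.20, fetal and stress -1.37, YAP and TEAD targets -0.44, calcium handling 0.09, intercalated disc 0.29 and receptors 0.13. The values in fibroblasts were S 1.27 and G2/M 2.39. Endothelial cells had S 1.68, G2/M 2.91, interferon -1.25, angiogenesis 0.00, capillary lipid transport 0.48 and Cenpa -0.13. In this setting a cluster of 362 2D2P and 5 control nuclei led by cell cycle genes stayed unnamed, so its nuclei were in no class. The libraries clustered separately gave differences of -6.99 points (fibroblast share), 0.797 points (endothelial share) and -10.0 points (macrophage share). For cardiomyocytes it gave fetal and stress -1.07. In fibroblasts it gave S 1.50, G2/M 3.87, interferon -2.33, activated fibroblast -0.30, resting fibroblast 0.06 and TGF-beta pathway -0.13. The values in endothelial cells were G2/M 4.26, angiogenesis 0.00 and endothelial activation -0.31. Macrophages had G2/M 4.20, inflammatory monocyte -0.67, lipid and repair macrophage -0.12 and antigen presentation -2.12. TMM scaling gave, in cardiomyocytes, adult sarcomere -0.41, fetal and stress -1.14, actin remodelling 0.34, SRF and MRTF targets 0.02, YAP and TEAD targets -0.46, cell cycle inhibitors 0.15, cardiac transcription factors 0.09, fatty acid 0.63, oxidative phosphorylation 0.36, calcium handling -0.01, intercalated disc 0.08, receptors 0.07 and p53 0.03. The total without mitochondrial genes and Malat1 gave, in cardiomyocytes, adult sarcomere -0.27. Equal weight per nucleus gave, in cardiomyocytes, G2/M 4.40. For fibroblasts it gave fibrillar matrix 0.13 and activated fibroblast 0.14. In endothelial cells it gave angiogenesis -0.05, endothelial activation -0.83 and capillary lipid transport 0.35. The values in macrophages were S 1.55, G2/M 2.74, resident macrophage -0.26 and lipid and repair macrophage -0.65. Nuclei thinned to 1000 UMIs gave, in cardiomyocytes, adult sarcomere -0.16, cell cycle inhibitors -0.03, fatty acid 0.87, oxidative phosphorylation 0.43, glycolysis 0.14, intercalated disc 0.18, S 1.75, G2/M 2.85 and interferon -0.27. Fibroblasts had immediate early -0.20, fibrillar matrix 0.15 and activated fibroblast 0.24. For endothelial cells it gave interferon -1.24, angiogenesis -0.02 and endothelial activation -0.68. In macrophages it gave S 1.33, G2/M 2.97 and resident macrophage -0.26. Free RNA subtracted gave, in cardiomyocytes, adult sarcomere -0.15, fetal and stress -1.07, dedifferentiation markers 0.00, SRF and MRTF targets 0.51, YAP and TEAD targets -0.48, cell cycle entry 2.19, calcium handling 0.25, intercalated disc 0.34, receptors 0.15, G2/M 5.36, interferon 0.00 and Ccnd3 6.87. The values in fibroblasts were S 1.48, G2/M 2.78, fibrillar matrix -0.16, activated fibroblast -0.18, resting fibroblast -0.32 and TGF-beta pathway -0.30. Endothelial cells had immediate early -1.09, angiogenesis -0.64, endothelial activation -1.81 and capillary lipid transport -0.14. A minimum of 1 UMI in each library gave, in cardiomyocytes, fetal and stress -1.23. For fibroblasts it gave activated fibroblast -0.15. In endothelial cells it gave endothelial activation -1.44. A minimum of 100 UMIs gave, in fibroblasts, interferon -1.82 and fibrillar matrix 0.11. The values in endothelial cells were S 1.44, interferon -1.38, immediate early -0.17 and endothelial activation -0.51. Macrophages had S 1.51 and G2/M 3.16. Male nuclei only gave differences of -12.3 points (macrophage share) and 6.39 points (cycling fibroblast nuclei). For cardiomyocytes it gave adult sarcomere -0.20, fetal and stress -1.06, intercalated disc 0.28, Uty 0.26, Kdm5d 0.10 and Eif2s3y 0.27. In fibroblasts it gave S 2.05, G2/M 3.13, late scar fibroblast -4.11, TGF-beta pathway -0.14 and Eif2s3y 0.07. The values in endothelial cells were S 1.1, interferon -1.84, angiogenesis -0.32, Kdm5d 0.18 and Eif2s3y 0.06. Macrophages had S 1.41, inflammatory monocyte 0.63, lipid and repair macrophage -0.12, Jund -0.15 and Eif2s3y 0.37. Cardiomyocyte clusters 17 and 19 left out gave differences of 1.48 points (cycling cardiomyocyte nuclei). For cardiomyocytes it gave adult sarcomere -0.18, fetal and stress -1.42, calcium handling 0.08, intercalated disc 0.27, S 2.25 and G2/M 2.96. At least 1 G2/M gene gave differences of 13.7 points (cycling cardiomyocyte nuclei), 22.3 points (cycling fibroblast nuclei), 33.0 points (cycling endothelial nuclei) and 32.7 points (cycling macrophage nuclei). At least 3 G2/M genes gave differences of 3.97 points (cycling cardiomyocyte nuclei), 4.41 points (cycling fibroblast nuclei), 13.6 points (cycling endothelial nuclei) and 10.2 points (cycling macrophage nuclei). Thinning to 500 UMIs gave differences of 3.77 points (cycling cardiomyocyte nuclei), 4.52 points (cycling fibroblast nuclei), 13.1 points (cycling endothelial nuclei) and 9.62 points (cycling macrophage nuclei). Thinning to 2000 UMIs gave differences of 8.92 points (cycling cardiomyocyte nuclei), 13.3 points (cycling fibroblast nuclei), 33.4 points (cycling endothelial nuclei) and 31.4 points (cycling macrophage nuclei).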

Other observations

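The test of free RNA was chosen after the levels it uses had been seen; the test of the adult list was fixed before. The genes named here were chosen after their values were seen.

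Beyond the classes compared, adipocyte-like nuclei were 0.114% (0.0569 to 0.204) of control and 1.87% (1.63 to 2.13) of 2D2P nuclei. The 216 nuclei of the 2D2P library held Ucp1, the uncoupling protein of brown fat, at 938 CPM and Cidea, a brown fat lipid droplet gene, at 284 CPM, where the 11 control nuclei had 0 UMIs of each. Smooth muscle-like nuclei were 1.09% (0.890 to 1.31) of control and 1.63% (1.41 to 1.88) of 2D2P nuclei, Schwann-like nuclei 0.248% (0.159 to 0.369) of control and 0.493% (0.373 to 0.638) of 2D2P nuclei, T or NK-like nuclei 0.435% (0.314 to 0.587) of control and 0.398% (0.291 to 0.530) of 2D2P nuclei and B-like nuclei 0.362% (0.253 to 0.503) of control and 0.259% (0.175 to 0.370) of 2D2P nuclei. Cardiomyocyte cluster 17 held 278 nuclei of the 2D2P and 2 of the control library, with the atrial genes Myl4 at 974.7 CPM, Nppa at 476 CPM and Mybphl at 230.5 CPM and the pacemaker channel gene Hcn4 at 64.0 CPM in the 2D2P nuclei. Cluster 19 held 230 nuclei, all of the 2D2P library, with Top2a at 654 CPM and Mki67 at 382.5 CPM.

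Genes whose level declines after birth were higher in the 2D2P library in the 4 main classes. Igf2, a fetal growth factor gene, had 54.4 against 0.624 CPM in cardiomyocyte-like and 102 against 2.67 CPM in fibroblast-like nuclei, and H19, its imprinted neighbour, 25.4 against 1.01 CPM and 75.1 against 5.80 CPM. The list held 16 genes and was not among the lists fixed beforehand, so its counts and medians are no independent check. Of its genes 2 (Igf2bp3 and Hmga2) are also in the dedifferentiation list and 1 (Cdkn1c) in the cell cycle inhibitor list. Of the measured genes 16 of 16 were higher in cardiomyocyte-like (median log2 ratio 2.54, 2.30 to 3.08), 16 of 16 in fibroblast-like (3.12, 2.86 to 3.41), 13 of 14 in endothelial-like (2.73, 2.38 to 3.43) and 13 of 14 in macrophage-like nuclei (2.32, 1.61 to 2.53). Meg3 was the exception in the endothelial-like and macrophage-like nuclei, at 171 against 248 CPM and 388 against 449.9 CPM. In endocardial-like, mesothelial-like, pericyte-like, smooth muscle-like, Schwann-like and lymphatic endothelial-like nuclei the medians lay between 1.48 and 3.14.

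Free RNA from cardiomyocytes is argued against as the source of this pattern. In the 2D2P library the list was higher in fibroblast-like than in cardiomyocyte-like nuclei by a median of 1.79 (1.64 to 1.94). In endothelial-like and macrophage-like nuclei it was higher by 0.71 (0.52 to 0.835) and 0.96 (0.53 to 1.12). Cardiomyocyte markers had medians of -2.31, -1.18 and -1.43 in the same order. The test covers cardiomyocytes as the source only, and free RNA from other classes was not tested. Hearts of a younger age in the 2D2P library cannot be told apart from an effect of the treatment on several cell types: the adult cardiomyocyte list had a median of -0.28 (-0.36 to -0.16), between the bounds of -0.5 and 0 set for this test, and with 1 library per group the heart and the treatment go together. Of the adult list 8 of 10 genes were lower (percentile 2.38), where all measured genes had a median of 0.16. TMM scaling shifted the median of all cardiomyocyte genes by -0.16, toward the lower bound. That list held Ckmt2 at 329 against 897 CPM and Ckm at 184 against 128 CPM in the 2D2P and control cardiomyocyte-like nuclei, and 3 of its 10 genes are also in the metabolic lists. An effect of the treatment itself was not tested and remains open, and so does a mix-up of samples, since the labels were taken as given.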
